A study of Arabidopsis thaliana with 11 samples.

How the data were processed

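RNA of Arabidopsis thaliana, accession Landsberg erecta, was measured on 11 Affymetrix ATH1 1-colour arrays, of which 3 held stigma, 4 ovary and 4 whole seedling RNA. Per the labels, floral buds were emasculated at stage 8, pistils were collected 1 day later, and the stigma was separated from the ovary by cutting. Seedlings had grown for 10 days on plates of Murashige and Skoog medium. The group of each array was taken from its title, because the descriptive text of the stigma arrays repeats that of the ovary arrays. The labels do not say whether arrays of 1 tissue came from separate plant cultures, so every p-value measures the spread between these samples, which may be in part technical.

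The deposited expression values are linear intensity values, 1 signal for each of 22810 probe sets on each array. The 2% trimmed mean of an array lay between 500.03 and 500.04 on all 11 arrays, so the authors had scaled every array to a common mean; this was read from the values, and the software is not given in the sources used here. The table holds no detection calls, 2 values of 0, and no pair of identical columns. The deposited run information of each array holds no expression values and counts as another kind of unit (other); it was used only to group arrays by the period of scanning and by chip lot. The 4 periods are called runs. Run A held stigma 1, ovary 1 and ovary 2; run B held stigma 2, stigma 3, ovary 3 and ovary 4; run C held seedlings 1 and 2; run D held seedlings 3 and 4. Chip lot 1 held stigma 1, ovary 1, ovary 2 and seedling 1, lot 2 held stigma 2, stigma 3, ovary 3, ovary 4 and seedling 2, and lot 3 held seedlings 3 and 4.

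After the 64 control probe sets were set aside, 22746 remained. A probe set was tested if its signal passed 144.2, the 40th percentile of all values, on at least 3 arrays, which kept 15524 and left out 7222. Values were analysed as the log2 of the signal plus 17.2, the 10th percentile of all values, so a log2 difference understates the change of dim transcripts. No further scaling was applied. One mean per tissue was fitted over all 11 arrays in limma 3.58.1 under R 4.3.3, with moderated variances that follow a trend with signal, 8 residual degrees of freedom and 5.19 prior degrees of freedom. A probe set was called for a comparison if its Benjamini-Hochberg adjusted p was under 0.05 and its difference was at least 2-fold. Probe sets called higher in 1 tissue than in both others form that tissue's set. All errors after a log2 difference are standard errors of the fit, and those after a mean signal are standard deviations over arrays. For arrays, the number of arrays limits the precision, and no counts underlie a value.

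Gene names came from the annotation supplied for the probe sets. It gave 1 gene for 13513 probe sets (59.4%) and several for 503, and 8730 were not listed in it; probe sets in these last 2 classes were counted but are not named. Of the probe sets with 1 gene, 13436 matched the reference gene table. Tested probe sets with 1 gene numbered 8496 and covered 8394 genes. No genome coordinates were used.

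The rule for named genes took, for each comparison, the 5 called probe sets with the largest positive and the 5 with the largest negative difference among those that name 1 gene and whose arrays do not overlap between the tissues. It took the 6 with the largest smaller difference for each tissue set, up to 3 called members of each gene list, or the member with the largest difference by value only where none was called, and 10 genes as a check of the labels. Only SLR1 and STIG1 of those 10 have a named probe set. Gene lists numbered 17 and held 314 genes, of which 65 were named on the array and 47 were tested. The 17 lists were stigma and papilla, stigma and style development regulators, transmitting tract, carpel and ovule regulators, flower MADS, embryo sac, cell cycle, photosynthesis, root, pollen, tapetum and anther, cuticle, wax and epidermis, expansin, Aux/IAA, jasmonate and wound, pathogenesis-related and antimicrobial, and reference genes. The 7 lists with at least 3 tested genes were tested by camera of limma against all other tested genes, with 1 probe set per gene and a preset correlation of 0.01. This made 21 tests adjusted together. The tested genes were 8 of 20 for stigma and style regulators, 4 of 24 for carpel and ovule regulators and 3 of 32 for cell cycle. They were 9 of 39 for photosynthesis, 3 of 21 for root, 3 of 37 for cuticle and 8 of 17 for expansin genes. A set result thus covers the tested members, not the whole list. The tests were repeated with a correlation estimated from the data and with fry, which tests a set against no change and is left out of the ranges of adjusted p over alternatives. A further 20 gene families with at least 8 tested members, formed from gene symbols, were chosen after the annotation had been seen and made 60 tests.

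RNA quality was measured as the log2 ratio of the 3' to the 5' control probe sets of actin and GAPDH on each array and compared by exact two-sided permutation tests. The groups, comparisons, named-gene rule, gene lists, thresholds and most alternative settings were fixed before the data were examined. The chip lot block, the RNA quality covariate, the removal of 3 arrays together and the second control probe sets were added after the data had been seen. The settings fixed beforehand changed the scaling (quantile, equal medians), the pseudocount (25th percentile, 69.3, or a floor), the filter (none, or the 60th percentile, 343.2), the variance trend, the arrays in the fit, the fold threshold (none or 4-fold), the probe sets per gene, the set test, and blocks for replicate number and run. They also averaged the arrays of each tissue and run, and left out each array in turn. Against seedling the run block entered the calls but not the set tests. The stricter filter left under 3 tested genes in the root and cuticle lists, so their ranges of adjusted p leave it out.

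The steps were tested on simulated data of 15524 probe sets. For stigma versus ovary, 85.1% of probe sets changed by 1.5 on the log2 scale were recovered, 91.0% of those changed by 2 and 100% of those changed by 3, and 3 unchanged probe sets were called. Camera called 20 of 20 shifted sets and 0 of 20 unshifted sets among 8394 genes. The simulated genes were drawn independently, in sets of 9, so this cannot show false calls that arise from correlation between genes. In the real lists the estimated correlation reached 0.51, for the cell cycle genes.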

Results

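Transcript levels were compared between the stigma, the ovary and the whole seedling of Arabidopsis, under a study title that names pollination. There were 3 stigma, 4 ovary and 4 seedling arrays. Values after ± are standard deviations of the signal over these arrays, and SE marks the standard error of a log2 difference. Differences are of log2(signal + 17.2), which understates those of dim transcripts. Where the signal of 1 tissue lay under 17.2, the 10th percentile of all values, on average or on at least 2 arrays, the difference is given as a bound (at least, or a bound), and such bounds have no order. The first principal component held 58.9% of the variance and separated seedlings from both pistil parts, and the second held 23.4% and separated stigma from ovary. Median signal per array was 216 ± 9.88 for stigma, 242 ± 12.2 for ovary and 223 ± 9.90 for seedling. Arrays of stigma and ovary had a mean rank correlation of 0.955 to 0.971 with their own tissue; seedlings 1 to 3 had 0.935 to 0.946 and seedling 4 had 0.896.

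**Figure D1:**
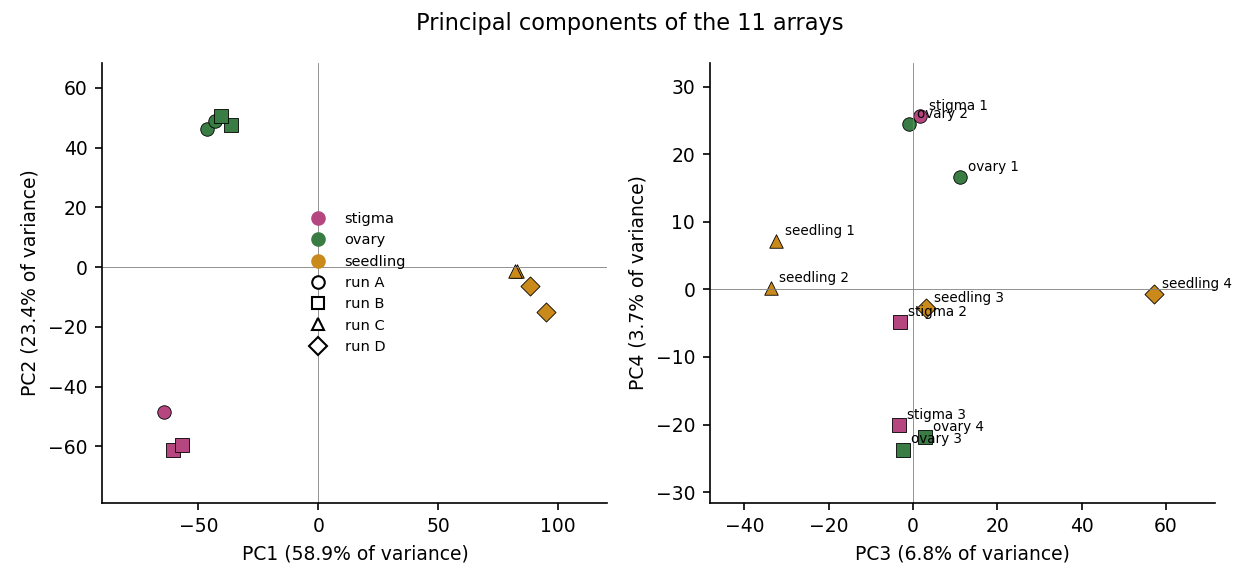
Scores of the 11 arrays on the first 4 principal components of the log2 signals, with the share of variance of each on its axis. Colours mark tissues and shapes mark runs; the left panel separates the 3 tissues, and in the right panel seedling 4 stands apart on the third component, which holds 6.80% of the variance.

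The first comparison asks which transcripts distinguish the stigma, the receptive tip of the pistil, from the ovary that holds the ovules. AT3G12000 (SLR1), a relative of the S-locus glycoproteins found in stigmas, had a signal of 13532 ± 978 in stigma and 607 ± 821 in ovary, a log2 difference of 5.27 (SE 0.63). The peroxidase gene AT5G19880 was higher in stigma by 5.99 (SE 0.74), with 15939 ± 2836 in stigma and 538 ± 844 in ovary. CYP79A2, which makes phenylacetaldoxime from phenylalanine, had 1573 ± 353 in stigma and 21 ± 30.2 in ovary, under 17.2 on all ovary arrays but ovary 1, a difference of at least 5.62 (SE 0.43). In the other direction SWEET9, a sucrose transporter known from nectaries, had 167 ± 20.6 in stigma and 5598 ± 1340 in ovary, a difference of −4.91 (SE 0.24). The terpene synthase gene AT3G25810 differed by −5.14 (SE 0.52), with 60.2 ± 75.9 in stigma and 2190.4 ± 1233 in ovary.

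In all, 2450 of 15524 probe sets were called, 973 higher and 1477 lower in stigma; 2398 of these did not overlap between the tissues. At 16-fold or more, 32 were higher and 8 lower. The median difference over all tested probe sets was −0.07, and setting the medians of the arrays equal moved it to 0.08, which raised the share of called probe sets that were higher in stigma from 39.7% to 52.6%. Both tissues were present in runs A and B. With run as a block 2538 probe sets were called, 2221 were called within run A and 2626 within run B. Within chip lot 1 and lot 2, 2080 and 2580 were called. Lots 1 and 2 divide the stigma and ovary arrays as runs A and B do, so lot is no separate check here. Run A and lot 1 had 1 stigma array, so its spread was taken from the other groups. The difference between the runs was called for 1 probe set by limma, that of LCR69, with 1237 at an unadjusted p under 0.05. LCR69 is given because it was the only one, outside the rule for named genes.

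Further genes far higher in stigma were AT5G11400 (difference of at least 5.97, SE 0.44), AT2G33850 (5.76, SE 0.996), AT4G00910 (at least 5.60, SE 0.50), AT3G55870 (at least 5.52, SE 0.36) and the peroxidase gene AT3G03670 (5.49, SE 0.41). Ovary 1 carried several of these transcripts well above the other ovary arrays. It had 1832.3 for SLR1, against 124 to 316.4 on the other ovary arrays, and 3960.3 for AT2G33850, against 79.2 to 94.6. Without ovary 1 the difference was 6.07 for SLR1, 6.95 for AT5G19880 and 7.07 for AT2G33850. Among genes far lower in stigma, AT1G56100 differed by −4.68 (SE 0.41), the subtilase gene AT4G21630 by −4.11 (SE 0.53), AT5G11420 by −3.90 (SE 0.44), AT3G56610 by −3.80 (SE 0.26) and AT1G02190, a relative of the wax gene CER1, by −3.71 (SE 0.45). Stigma 1 carried more of some ovary transcripts than the other stigma arrays. Without it the difference was −4.82 for AT4G21630 and −4.49 for AT1G02190; without stigma 3 it was −3.42 for AT4G21630 and −5.91 for AT3G25810. Without stigma 1, ovary 1 and seedling 4 together it was −4.56 for AT5G11420 and at least 6.24 for CYP79A2.

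Of the 8 tested regulators of stigma and style development, 4 were called higher in stigma than in ovary and none was called lower. They were YUC4, an auxin synthesis gene (537 ± 198 and 83.6 ± 22.6, difference 2.41, SE 0.29), and the NGATHA genes NGA3 (2.14, SE 0.35), NGA1 (1.78, SE 0.26) and NGA4 (1.15, SE 0.26). SHI, given outside the rule for named genes, was lower by less than 2-fold (−0.67, SE 0.22, adjusted p = 0.0328). Before any fold threshold 6 of 8 passed 0.05, SHI among them in the opposite direction, both adjusted over the list alone and over all genes. The members were higher in stigma as a set, with adjusted p = 0.00568 and a median difference of 0.82, 0.81 in run A and 0.88 in run B, and adjusted p = 0.00734 with run as a block. This call ended with the stricter filter (adjusted p = 0.0725) and with an estimated correlation (adjusted p = 0.0869); over all alternatives adjusted p ran from 0.00296 to 0.0869. SPT, in this list and in that of the transmitting tract, was not called (454 ± 60.6 in stigma and 380 ± 45.7 in ovary).

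Of 4 tested carpel and ovule regulators, 2 were lower in stigma. INO, which acts in the outer ovule integument, had 195 ± 55.5 in stigma and 579 ± 42.4 in ovary (difference −1.52, SE 0.27). ALC, which acts in fruit opening, had 473 ± 37.2 and 1100 ± 210 (difference −1.17, SE 0.23), and its call ended with the RNA quality ratio as a covariate (−0.92). Over the list alone 4 of 4 passed an adjusted p of 0.05, against 3 over all genes. The set was lower, with adjusted p = 0.0105, a median of −1.02, medians of −0.73 in run A and −1.23 in run B, and adjusted p = 0.0120 with run as a block. It was not called with an estimated correlation (adjusted p = 0.0977, the highest of all alternatives, the lowest being 0.00601). All 3 tested cell cycle genes were lower in stigma: PRL, which encodes the replication factor MCM7 (346 ± 54.5 and 1068 ± 232, difference −1.56, SE 0.24), and the Aurora kinase genes AUR2 (−1.19, SE 0.21) and AUR1 (−1.17, SE 0.21). AUR2 fell short of 2-fold with the larger pseudocount (−0.98). The set had adjusted p = 0.00911, medians of −0.94 and −1.36 in runs A and B, and adjusted p = 0.00934 with run as a block. With an estimated correlation adjusted p = 0.148, the highest of all alternatives, and the lowest was 0.00296. All 3 passed 0.05 both over all genes and adjusted over the list alone.

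None of the 9 tested photosynthesis genes was called between stigma and ovary. PSBW had 8411 ± 643 in stigma and 6001 ± 1250 in ovary, and the set had adjusted p = 0.528 with a median of 0.01, 0.24 in run A and −0.07 in run B; its direction turned under quantile scaling (adjusted p = 0.654, with 0.281 to 0.992 over all alternatives). Of 8 expansin genes, which encode cell wall loosening proteins, EXLA1 was higher in stigma (9390 ± 1007 and 765 ± 385, difference 3.72, SE 0.75), EXPA8 was higher (1.84, SE 0.30) and EXPA9 was lower (−1.67, SE 0.20), with adjusted p = 0.528 for the set and medians of −0.15 and 0.50 in runs A and B. Of 3 cuticle genes, WSD1, a wax ester synthase gene, was lower (1623 ± 296 and 3340.4 ± 132, difference −1.05, SE 0.19). Its call ended with equal medians (−0.90), with averaged arrays (−0.98), with chip lot as a block (−0.997), without stigma 2 (−0.9997) and without stigma 3 (−0.95). The cuticle set was not called (adjusted p = 0.0629, medians of −0.80 and −1.07 in runs A and B). It passed with the larger pseudocount (adjusted p = 0.0302), with no filter (0.0335) and with the arrays of 2 tissues alone (0.0460). It also passed with the RNA quality covariate (0.0269), without stigma 1 (0.0398) and without seedling 1 (0.0405). Its adjusted p ran from 0.0269 to 0.211 over all alternatives that tested it. None of the 3 root genes was called, with EXPA7 at 48.2 ± 41.3 and 64.7 ± 13.0, and adjusted p = 0.664 for the set. None of these sets was called with an estimated correlation.

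Lists with fewer than 3 tested members were read gene by gene. CES (HAF), a transcription factor gene of the transmitting tract, was higher in stigma, with 11661 ± 2637 against 2896 ± 591 (difference 2.003, SE 0.25). THI2.1, a jasmonate-responsive thionin gene, was lower, with 4423 ± 4046 against 14565 ± 1923 (difference −2.08, SE 0.41); the difference was −0.62 in run A and −2.83 in run B, and −2.78 without stigma 1. STIG1, a stigma gene, lay below the filter in all tissues (49.8 ± 44.1 in stigma, 28.7 ± 4.96 in ovary and 22.6 ± 3.63 in seedling). Pollen and anther transcripts were dim. Of 6 pollen genes only TUA1 was tested, and it was not called (567 ± 84.0 in stigma and 588 ± 63.6 in ovary). The highest signal of the others was 153.7 for ANX2 on a stigma array. Below the filter, AT59 had 111 ± 24.7 in stigma, 36.5 ± 20.9 in ovary and 6.88 ± 1.78 in seedling, without overlap. Mean signals of ANX2 (84.7, 21.3 and 31.8) and ACT12 (38.2, 11.7 and 5.0) were also highest in stigma, but their arrays overlapped. HTR10 (16.1, 15.8 and 23.0) and ANX1 (6.77, 4.95 and 4.4) were near the floor. Whether pollen was on the stigma samples was not tested. The tapetum genes A9 and AMS stayed under 100 on every array. Of 4 embryo sac genes AGL61 was tested and was not called (235 ± 60.5 and 198.0 ± 63.3), and EC1.2, below the filter, had 125 ± 37.3 in ovary. IAA18 (402 ± 29.3 and 620 ± 64.5) and the antimicrobial gene THI2.2 (27.7 ± 9.62 and 23.98 ± 18.8) were not called. The reference genes AT4G34270 (806 ± 114 and 723 ± 86.0) and SAND (659 ± 50.4 and 657 ± 71.4) were not called either. No flower MADS gene of the lists had a named probe set.

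**Figure D2:**
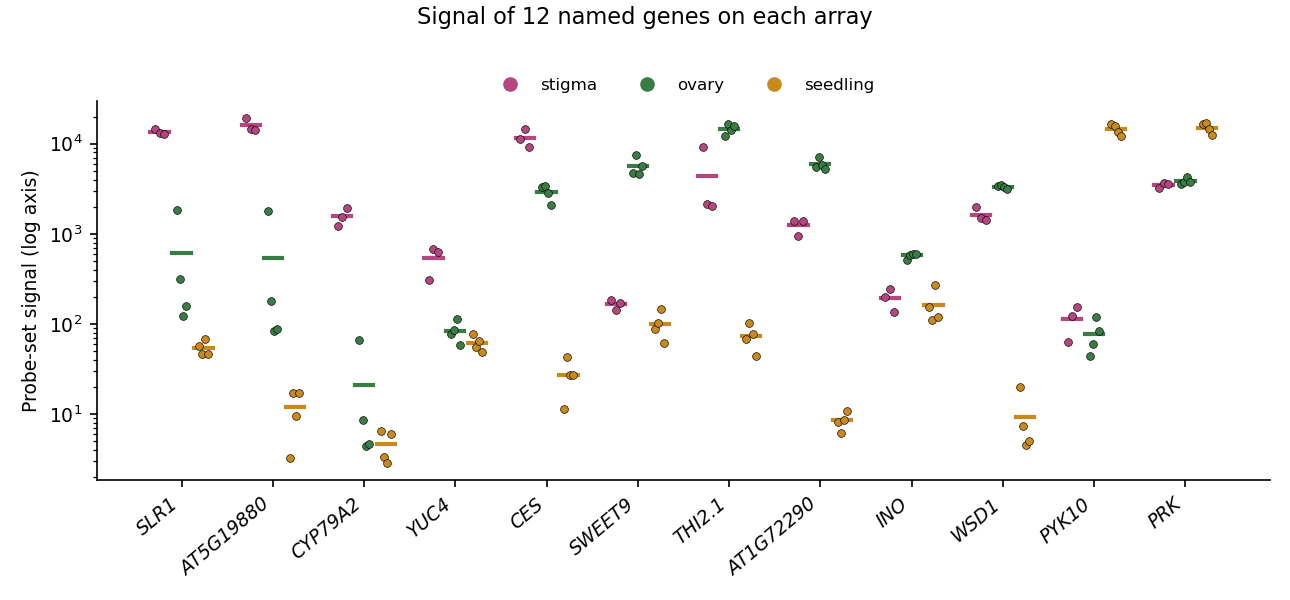
Probe-set signal of 12 named genes on a log axis, 1 point per array and a bar at the mean of each tissue (3 stigma, 4 ovary and 4 seedling arrays). SLR1, AT5G19880, CYP79A2 and YUC4 are highest in stigma, SWEET9, THI2.1, AT1G72290 and INO in ovary, and PYK10 and PRK in seedling; ovary 1 is the highest of the ovary points for the first 3, with 1832.3 for SLR1.

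The second comparison sets the stigma against the whole seedling. Among transcripts far higher in stigma, AT5G19880 had 11.9 ± 6.84 in seedling, a log2 difference of at least 9.12 (SE 0.74), and OCT1, a gene for a carnitine transporter, had 5938 ± 1601 in stigma and 6.9 ± 3.43 in seedling (at least 7.92, SE 0.19). With the larger pseudocount these differences were 7.61 and 6.27. CES, with 27.2 ± 13.2 in seedling, differed by 8.06 (SE 0.25), the subtilase gene SBT4.13, with 14932 ± 1611 and 55.0 ± 9.92, by 7.70 (SE 0.14) and SLR1, with 54.7 ± 10.4 in seedling, by 7.57 (SE 0.63). Far lower in stigma than in seedling were AT2G05540 (19.4 ± 1.46 and 5120.5 ± 3111, difference −6.93, SE 0.52) and PYK10, the β-glucosidase gene of root endoplasmic reticulum bodies (114 ± 46.3 and 14458 ± 1970.03, −6.84, SE 0.28). So were AT1G23130 (−6.48, SE 0.25), the lectin gene JAL34 (−6.08, SE 0.19) and AT1G49500 (−6.04, SE 0.36).

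In this comparison 4053 probe sets were called, 1707 higher and 2346 lower in stigma. The share that was higher, 42.1%, was 44.6% with equal medians and 50.98% with no fold threshold. There were 150 higher and 119 lower by 16-fold or more, and 3916 without overlap. Runs C and D held seedlings alone, so no run holds both tissues; with run as a random block 3951 were called. Chip lots 1 and 2 held both tissues. With lot as a block 4156 were called, 3886 within lot 1 and 3924 within lot 2; lot 1 had 1 array of each tissue and lot 2 had 1 seedling, so their spread was taken from the other groups. The control ratios moved with tissue. The log2 ratio of 3' to 5' signal was 3.18 ± 0.88 in stigma, 2.17 ± 0.60 in ovary and 1.99 ± 0.53 in seedling for actin, and 1.495 ± 0.67, 0.82 ± 0.19 and 0.38 ± 0.13 for GAPDH. Exact two-sided permutation p for actin was 0.143 for stigma and ovary, 0.0571 for stigma and seedling and 0.714 for ovary and seedling, and for GAPDH it was 0.0571, 0.0286 and 0.0286, where 0.0286 is the smallest possible. After adjustment over the 6 tests the exact p ran from 0.0857 to 0.714, which does not show equal RNA quality. The mean of stigma was the highest of the 3 tissues in all 5 control ratios measured. Stigma reached the smallest p, unadjusted, against each other tissue for ubiquitin (1.59 ± 0.44, 0.68 ± 0.22 and 0.77 ± 0.09 in stigma, ovary and seedling) and for the second actin probe sets (1.45 ± 0.71, 0.74 ± 0.24 and 0.40 ± 0.06). Without stigma 1 the actin difference between stigma and ovary dropped from 1.01 to 0.54, and the GAPDH difference from 0.67 to 0.28.

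Of 9 tested photosynthesis genes, 6 were lower in stigma than in seedling and none was higher. The Calvin cycle gene PRK had 3472 ± 244 in stigma and 15067 ± 2060 in seedling (difference −2.10, SE 0.13), the antenna gene LHCB4.2 had 1660.2 ± 313 and 7634 ± 1810 (−2.18, SE 0.19) and SBPASE differed by −1.57 (SE 0.21). All 9 passed 0.05 both over all genes and adjusted over the list alone. The set had adjusted p = 2.0e-06, a median of −1.48, and medians of −1.37 and −1.53 in chip lots 1 and 2. With an estimated correlation adjusted p = 0.0840, the highest of all alternatives, and the lowest was 2.4e-07. Of 3 root genes, PYK10 and EXPA7, a root hair expansin gene, were lower (EXPA7 −1.80, SE 0.36, and −1.16 with the larger pseudocount). The root set had adjusted p = 0.00911 and medians of −1.10 and −1.93 in lots 1 and 2. With an estimated correlation adjusted p = 0.0840, the highest of all alternatives that tested it, and the lowest was 0.00331. All 3 passed 0.05 over all genes and adjusted over the list alone.

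Regulators of stigma and style development were higher than in seedling for 3 of 8, YUC4 (2.75, SE 0.29), NGA1 (2.16, SE 0.26) and NGA3 (1.44, SE 0.35), and 6 of 8 passed 0.05 over all genes and adjusted over the list alone. The set had adjusted p = 0.00911 and medians of 0.80 and 0.82 in chip lots 1 and 2. It was not called with the stricter filter (adjusted p = 0.139) or with an estimated correlation (adjusted p = 0.0970), over a range of 0.00329 to 0.139. All 3 cuticle and epidermis genes were higher: WSD1 (at least 5.97, SE 0.19), SHN3, a regulator of cutin and wax genes (218 ± 32.5 and 16.3 ± 1.81, at least 2.81, SE 0.19, and 1.74 with the larger pseudocount), and CR4 (ACR4), an epidermal receptor kinase gene (1.01, SE 0.29). The call of CR4 ended in 8 alternatives: with the larger pseudocount (0.76), the replicate block (0.95), the removal of stigma 1, ovary 1 and seedling 4 together (0.79), and without stigma 1 (0.86), stigma 2 (0.89), seedling 2 (0.84) and seedling 4 (0.94), and with the RNA quality covariate (0.53). The cuticle set had adjusted p = 0.00568 and medians of 3.04 and 2.78 in lots 1 and 2. With an estimated correlation adjusted p = 0.0869, the highest of all alternatives that tested it, and the lowest was 0.00172.

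Of the 4 carpel and ovule regulators ALC was higher in stigma than in seedling (473 ± 37.2 and 191 ± 61.1, difference 1.28, SE 0.23), and its call ended with chip lot as a block (0.92); the set had adjusted p = 0.179, and 0.346 with an estimated correlation. No cell cycle gene was called (AUR1 292 ± 36.4 and 550.4 ± 166, difference −0.84, which passed 2-fold with chip lot as a block at −1.18 and without stigma 1, ovary 1 and seedling 4 at −1.06), with adjusted p = 0.246 for the set. Of the expansin genes EXLA1 was higher (4.08, SE 0.75, and 5.01 without seedling 4, which carried 3830.7 against 206 to 343.9 on the other seedlings); the set had adjusted p = 0.645. THI2.1 was higher by 5.29 (SE 0.41), and by 4.58 without stigma 1, and THI2.2 was lower by −4.55 (SE 0.38). IAA18 was not called (difference −0.99, SE 0.23), but was past 2-fold and called with a floor (−1.02), run as a block (−1.01), averaged arrays (−1.01) or the RNA quality covariate (−1.22), and without stigma 2 (−1.05), seedling 1 (−1.08) or seedling 2 (−1.16). AGL61, TUA1 and AT4G34270 were not called, with differences of 0.27, −0.41 and 0.25.

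The third comparison sets the ovary against the whole seedling. AT1G72290, a Kunitz-type protease inhibitor gene, had 5949.6 ± 830.1 in ovary and 8.55 ± 1.97 in seedling, a log2 difference of at least 7.85 (SE 0.16), and of 6.26 with the larger pseudocount. GILT, a thiol reductase gene, had 13156 ± 1289 and 54.3 ± 17.5 (7.55, SE 0.39), THI2.1 had 14565 ± 1923 and 73.2 ± 23.9 (7.36, SE 0.38), WSD1 had 3340.4 ± 132 and 9.33 ± 7.35 (at least 7.02, SE 0.18) and the sesquiterpene synthase gene AT5G44630 had 4864 ± 234 and 38.3 ± 14.4 (6.49, SE 0.19). Lower in ovary were PYK10 (77.3 ± 32.8 in ovary, difference −7.31, SE 0.26), JAL34 (56.4 ± 6.11 and 6722 ± 474, −6.52, SE 0.17), AT3G05730 (43.4 ± 20.1 and 4140.3 ± 526, −6.15, SE 0.22), AT2G05540 (−5.99, SE 0.48) and AT1G23130 (−5.95, SE 0.23).

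In this comparison 3537 probe sets were called, 1720 higher and 1817 lower in ovary. The share that was higher, 48.6%, was 40.7% with equal medians and 58.9% with no fold threshold. There were 93 higher and 81 lower by 16-fold or more, and 3397 without overlap. With run as a random block 3436 were called. With chip lot as a block 3414 were called, 3516 within lot 1 and 3063 within lot 2, each with 1 seedling array, whose spread was taken from the other groups. Between the runs of a tissue, limma called 0 probe sets for ovary (2731 at an unadjusted p under 0.05) and 689 for seedling.

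Photosynthesis genes were lower in ovary for 8 of 9, with PRK at −1.97 (SE 0.12), LHCB4.2 at −1.89 (SE 0.18) and SBPASE at −1.80 (SE 0.19), and all 9 passed 0.05 over all genes and adjusted over the list alone. The set had adjusted p = 1.0e-07 and medians of −1.48 and −1.43 in chip lots 1 and 2. With an estimated correlation adjusted p = 0.0840, the highest of all alternatives, and the lowest was 2.0e-08. All 3 root genes were lower: PYK10, EXPA7 (−1.31, SE 0.33) and EXPA18 (−1.19, SE 0.23). With the larger pseudocount EXPA7 (−0.93) and EXPA18 (−0.90) lost their calls, as did EXPA18 without ovary 2 (−0.999). With averaged arrays EXPA7 kept its difference but not its adjusted p (0.0611). The root set had adjusted p = 0.00619 and medians of −1.69 and −1.01 in lots 1 and 2. With an estimated correlation adjusted p = 0.0840, the highest of all alternatives that tested it, and the lowest was 0.00296. All 3 passed 0.05 over all genes and adjusted over the list alone.

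Carpel and ovule regulators were higher in ovary for 3 of 4: ALC (1100 ± 210 and 191 ± 61.1, 2.45, SE 0.21), INO (1.80, SE 0.25) and TSO1 (1511 ± 99.1 and 529 ± 92.7, 1.5, SE 0.15), with 4 of 4 at 0.05 over all genes and adjusted over the list alone. The set had adjusted p = 0.00734 and medians of 1.52 and 1.78 in lots 1 and 2. With an estimated correlation adjusted p = 0.0873, the highest of all alternatives, and the lowest was 0.00461. All 3 cuticle genes were higher: WSD1, SHN3 (at least 3.79, SE 0.17) and CR4 (1.47, SE 0.27). Their set had adjusted p = 0.00328 and medians of 3.84 and 3.85 in lots 1 and 2. With an estimated correlation adjusted p = 0.0840, the highest of all alternatives that tested it, and the lowest was 3.4e-04. CES was higher by 6.06 (SE 0.23) and SLR1 by 2.30 (SE 0.58), the latter by 1.499 without ovary 1, and THI2.2 was lower (−4.75, SE 0.35, a bound).

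Of the stigma and style regulators SHI was higher in ovary (252 ± 11.1 and 102 ± 9.79, 1.17, SE 0.21), but not past 2-fold with the larger pseudocount (0.90), and the set had adjusted p = 0.715. Of the 3 cell cycle genes PRL was higher (1.54, SE 0.22), with adjusted p = 0.235 for the set. Of the expansin genes EXPB3 (1.44, SE 0.45) and EXPA15 (1.12, SE 0.39) were higher and EXPA8 was lower (342 ± 134 and 1568 ± 655, −2.12, SE 0.28). Without seedling 4 the difference dropped to 0.83 for EXPB3 and 0.63 for EXPA15, and with chip lot as a block to 0.54 and 0.32, and without stigma 1, ovary 1 and seedling 4 to 0.84 and 0.70, and neither was then called. EXPA15 stayed past 2-fold but not under an adjusted p of 0.05 with run as a block (adjusted p = 0.0571), with averaged arrays (0.0694), and without ovary 2 (0.0621), ovary 4 (0.0576) or seedling 3 (0.0598). The expansin set had adjusted p = 0.792, and its direction turned with chip lot as a block (adjusted p = 0.964) and without ovary 2 (adjusted p = 0.987), within 0.632 to 0.987 over all alternatives. AGL61, TUA1, IAA18 and AT4G34270 were not called, with differences of 0.02, −0.35, −0.39 and 0.10.

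**Figure D3:**
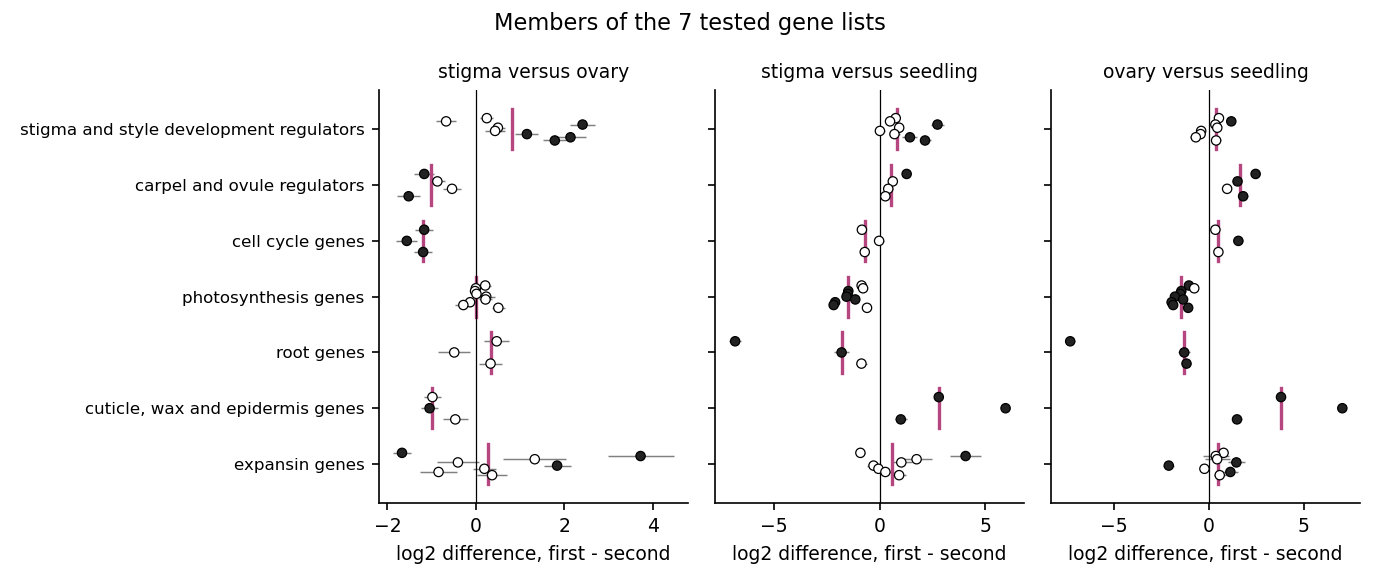
Log2 differences of the tested members of the 7 gene lists with at least 3 tested genes, 1 panel per comparison, with standard errors as grey lines. Filled points were called, open points were not, and the coloured line is the median of the list, such as −1.48 for photosynthesis genes in stigma against seedling.

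Sets of transcripts above both other tissues were counted last. The stigma set held 680 probe sets, against 107 if the component comparisons were independent, with 201 at least 4-fold and 25 at least 16-fold above both. The ovary set held 599 (164 if independent), with 144 and 6, and the seedling set held 1389 (275 if independent), with 500 and 62. Genes named for the stigma set were AT5G19880, AT5G11400, CYP79A2, AT3G55870, AT3G03670 and AT4G00910. Those of the ovary set were SWEET9, with 99.6 ± 35.5 in seedling, AT1G56100, AT3G25810, AT4G21630, AT3G56610 and AT1G02190, which had 4.73 ± 2.08 in seedling. Those of the seedling set were PYK10, JAL34, AT2G05540, AT1G23130, the peroxidase gene AT4G30170 (1640 ± 286 in seedling and 8.53 ± 6.96 in stigma) and AT4G38080 (910 ± 91.2 and 4.93 ± 2.11). When the 4 arrays of the tissue itself were split into pairs, 1 pair for each of its comparisons, the ovary set held 525 to 567 probe sets and the seedling set 1208 to 1315; the 3 stigma arrays do not allow such a split. In 20 simulated data sets with no tissue difference each set held 0 probe sets. Hardly any probe set is called there in a single comparison, so 0 follows from the setting and gives no overlap to compare with. Both comparisons of a set share the arrays of its tissue, so they are not independent and overlap for that reason too. For the stigma set the part of the overlap that comes from sharing was not measured.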

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

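The tests of the 3 patterns weighed here (stigma transcripts in ovary 1, ovary transcripts in stigma 1, and seedling 4) were chosen after the values had been seen, while the splits of the samples were planned. For stigma versus ovary, 1 of the 35 splits of the arrays, the real one, gave as many calls (2493 in a fit of these arrays alone, highest other 1). Splits that mix the tissues move the tissue difference into the spread, so they call few probe sets by construction. The share of 1 in 35 is also the smallest that this test can give. A chance division of these arrays is argued against, but chance between plants is not, as the arrays may be technical repeats. The same holds for stigma versus seedling (1 of 35, real 3981), where the split of seedlings 1, 2 and 3 from all other arrays, which holds most of the tissue difference, called 495, and for ovary versus seedling (1 of 35, real 3519, highest other 0). For sets above both other tissues, 1 of 100 random splits of the 11 arrays gave as many as the stigma set (680, highest other 0) and 1 of 100 as the seedling set (1389, highest other 0). For the ovary set (599) it was 2 of 100; the other split, with 1466, had all 4 seedlings as the ovary group and so follows the tissue structure. Splits that kept the 4 ovary arrays together but mixed stigma with seedling arrays gave 577 and 542 for the ovary set. Its size thus says little about the division of stigma from seedling. For the stigma and seedling sets a chance division of the arrays is argued against, with the same limits. For the ovary set this covers only the division of the ovary arrays from all others. For the 11 called list tests it was 4 of 100; the highest other was also 11, in 3 splits that mix the tissues, so chance is not clearly excluded there.

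Ovary 1 carried stigma transcripts above the other ovary arrays. It was far above the rest for AT5G19880 (1802, next 179), AT5G11400 (101.1, next 16.9), AT2G33850 (3960.3, next 94.6), CYP79A2 (66.2, next 8.6), AT3G12000 (SLR1, 1832.3, next 316.4), AT3G55870 (62.6, next 12.2) and the seedling-high AT2G05540 (187.7, next 39), and below it for GILT (11236.1, next 13621.5) and IAA18 (523.6, next 644.1). Of 77 probe sets at least 8-fold higher in stigma, chosen without ovary 1, 76.6% were highest in ovary 1, where an even share is 25%. Their median excess was 4.27% of the stigma level (quartiles 2.68 to 6.92). Of the 20 most abundant 17 were highest in ovary 1, with an excess of 2.33% to 27.2%. The choice required low signal in ovary 2 to 4, which favours ovary 1, so 25% is not the chance rate. No other ovary array was left out in this way for comparison. Ovary 2, of the same run and lot, had a median of 6.23% of the stigma level, near ovary 3 (5.44) and ovary 4 (5.76) and below ovary 1 (10.97). As the choice also favoured low signal in ovary 2, this speaks only weakly against array run or chip lot. RNA quality is argued against by the 3' to 5' ratio of ovary 1 (1.41), within those of the other ovary arrays (1.197 to 2.07). Stigma tissue left on the ovary 1 sample may be a source, as a hypothesis, but the excess is uneven for whole stigma in 1 proportion, with 27.2% for AT2G33850 and 7.61% for SBT5.4; the limits of 8-fold and 75% were set after the values were known, and 76.6% lies close to that bound. A difference in the ovary 1 plants themselves was not tested.

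Stigma 1 carried ovary transcripts above stigma 2 and 3. Of 156 probe sets at least 4-fold higher in ovary, chosen without stigma 1, 75% were highest in stigma 1, where an even share is 33.3%. This lies exactly at a bound set after the values were known. The median excess was 8.50% of the ovary level (quartiles 3.54 to 13.8). The choice required low signal in stigma 2 and 3, which favours stigma 1, so 33.3% is not the chance rate. RNA quality, for which stigma 1 had the highest ratio (3.20, others 1.77 to 2.05), is argued against as the whole cause by 487 probe sets higher in seedling, of which 30.2% were highest in stigma 1, with a median excess of −0.56%. Ovary tissue left on stigma 1 may be a source, but not whole ovary in 1 proportion: among the 20 most abundant probe sets the excess was 48.1% of the ovary level for THI2.1 and 0.44% for SWEET9 (183 in stigma 1, 173 on the next stigma array). Tissue next to the cut, and a different state of the stigma 1 plants, stay open and were not tested.

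Seedling 4 stood apart from the other seedlings and was an extreme value for EXLA1 (3830.7, next 343.9), AT4G00910 (92.2, next 27.4), AT4G21630 (54, next 7.3) and TSO1 (390.6, next 561.5). Array run or chip lot as the whole cause is argued against by 1049 probe sets that differed at least 2-fold between seedlings 3 and 4, of 1 run and lot, against 177 between seedlings 1 and 2. The mean 3' to 5' ratio of seedling 4 (1.45) lay within those of the other seedlings (0.85 to 1.48), where 1.48 is seedling 3 alone. Its actin ratio (2.49) was the highest of the seedlings. Its median signal (208, others 226 to 230) and its percent of probe sets above the filter (57.8, others 60.5 to 61.2) were the lowest. RNA quality thus stays open. A candidate explanation is sugar starvation or darkness of the seedling 4 plants. All 6 tested genes of a starvation list were highest there, with a median log2 excess of 2.06, at percentile 100 of 10000 random lists. Random lists hold unrelated genes, and a list whose genes move together can reach an extreme percentile on 1 array. Seedling 3, of the same run and lot, lay between for all 6, such as MCCA (668, 620.0, 1103 and 5562 in seedlings 1 to 4). These genes thus follow the run in part. The list was written after some genes of seedling 4 had been seen, and the samples have no group that gives a biological explanation, so none was tested by design.

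The remaining extreme arrays were ovary 2 for AT3G25810 (4029.3, next 1767.5), AT5G11420 (1464.7, next 519.7) and EXPA8 (541.6, next 300.3), seedling 3 for AT1G56100 (29.7, next 7.8), seedling 1 for OCT1 (12, next 5.6) and seedling 2 for AT3G55870 (17.6, next 10.2). Of 128 groups of 4 values tested for an extreme array, 19 had one, 12 in ovary (9 of them ovary 1) and 7 in seedling (4 of them seedling 4). For independent normal values chance gives 1 in 20, or 6.4. Most of these values were linear signals of genes measured on the same arrays, so 6.4 is not the chance rate here. Some extreme values lay near or under 17.2, such as those of OCT1 and AT3G55870. LCR69 was lower in stigma than in ovary in both runs, and the gap was smaller by 1.85 on the log2 scale in run A. Its signal was 4297 in stigma 1, 1361 and 1513 in stigma 2 and 3, and 10064 to 12637 in ovary. Stigma 1, which carried ovary transcripts, was the only stigma array of run A, so run and array cannot be told apart here.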

How the results depend on the processing

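The chip lot block, the RNA quality covariate, the removal of stigma 1, ovary 1 and seedling 4 together, and the second control probe sets were chosen only after the results had been seen. Counts stayed within 1.5 times the reported ones under both scalings, both pseudocount changes, both filters, no variance trend, fits of 2 tissues alone, the replicate, run and chip lot blocks, averaging, the covariate and the 3-array removal: 1867 to 2757 for stigma versus ovary, 3128 to 4741 for stigma versus seedling, 2698 to 4168 for ovary versus seedling, 580 to 805 for the stigma set, 450 to 666 for the ovary set and 1048 to 1621 for the seedling set. They moved with the fold threshold and with the probe sets taken. With no fold threshold they were 5381, 7644 and 8050 for the comparisons and 1501, 1784 and 2413 for the sets of stigma, ovary and seedling; with 4-fold 622, 1445, 1134, 201, 144 and 500; with one probe set per gene, which also drops those that do not name 1 gene, 1214, 1994, 1803, 353, 297 and 680, where 1227, 2030, 1821, 355, 298 and 688 of the reported calls name 1 gene. Called list tests numbered 11, and 5 with the filter at the 60th percentile, which tests fewer genes, 0 with an estimated correlation (adjusted p of 0.0840 or more) and 16 with fry, which asks a different question. Leaving out each array in turn gave 2317 to 2507, 3956 to 4092, 3436 to 3714, 664 to 701, 556 to 627, 1334 to 1448 and 11 to 12 list tests. Titles share replicate numbers across tissues. Residuals of equal numbers correlated at −0.08 to 0.26, and 2 of 10 pairs passed 0.1. Both were stigma and ovary pairs of 1 run, stigma 1 with ovary 1 (0.22) and stigma 3 with ovary 3 (0.26). Stigma 1 correlated as much with ovary 2 (0.26), of the same run. The 6 stigma and ovary pairs of 1 run gave −0.007 to 0.26, and the 6 others −0.29 to −0.03. Residuals thus followed run, and the numbers showed no pairing beyond it. The replicate block gave 2514, 4039, 3552, 678, 634 and 1396, and kept 2328 of 2450, 3857 of 4053 and 3535 of 3537 calls. Without the 3 arrays, 2574, 4053 and 3351 were called, with 2263, 3640 and 3083 of the reported calls kept. With the covariate 2037 of 2450, 3261 of 4053 and 3366 of 3537 calls were kept, and 4 of the 4053 had the opposite sign.

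Of 112 comparisons of genes taken by the rule 96 were called. Of these, 86 kept their call under every alternative that keeps the 2-fold threshold and tests the gene. The other 10 are named beside their values. A gene that a filter removes is not counted as lost: NGA3, at most 293.2, was not tested at the filter of 343.2. The rule took genes with large differences, so this stability is in part a result of the choice. Directions turned for uncalled genes and sets, and the cause was not tested. AGL61 in ovary against seedling was −0.025 with quantile scaling, −0.090 with equal medians, −0.17 with chip lot as a block, and −0.14 to 0.22 over single arrays left out, negative without ovary 3, ovary 4, seedling 3 or seedling 4; between stigma and seedling it was −0.0050 with chip lot as a block. AT4G34270 in ovary against seedling was −0.0097 with equal medians. TUA1 in stigma against ovary was 0.0071 with quantile scaling, 0.095 with equal medians, 0.0082 with the replicate block, 0.058 without the 3 arrays and −0.17 to 0.034 over single arrays left out, and in ovary against seedling 0.016 with chip lot as a block. The photosynthesis set in stigma against ovary turned with quantile scaling (adjusted p = 0.654), and the expansin set in ovary against seedling with chip lot as a block (0.964) and without ovary 2 (0.987, with 0.632 to 0.987 over single arrays left out). Leaving out each array gave actin ratio differences of 0.54 to 1.40 (stigma and ovary), 0.71 to 1.57 (stigma and seedling) and −0.12 to 0.34 (ovary and seedling), the last reversed without ovary 2 (−0.12) and seedling 2 (−0.006); GAPDH gave 0.28 to 0.87, 0.72 to 1.31 and 0.35 to 0.50. The second control probe sets gave differences of the same sign in all 6 ratio comparisons. Signal over background limits 7222 probe sets, left untested as dim, and list genes such as STIG1 among them.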

Other observations

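The gene family tests here were chosen only after the annotation had been seen, and their 60 tests were adjusted together. Of 13 tested SWEET sugar transporter genes, 6 were lower in stigma than in ovary and none was higher: SWEET9 (log2 difference −4.91, SE 0.24), SWEET4 (−2.83, SE 0.21), SWEET3 and SWEET8 (−1.83 each, SE 0.22 and 0.19), and SWEET17 and SWEET11 (−1.27 each, SE 0.20 and 0.29). The family had adjusted p = 0.00446 and a median of −0.60, with −0.85 and −0.68 within chip lots 1 and 2, which divide these arrays as runs A and B do. It was not called with an estimated correlation (adjusted p = 0.806). Of 10 bZIP transcription factor genes, 3 were higher in stigma than in ovary, bZIP44 (1.59, SE 0.14), bZIP58 (1.13, SE 0.29) and BZIP17 (1.13, SE 0.15), with adjusted p = 0.00446, a median of 0.50, medians of 0.66 and 0.58 within lots 1 and 2, and adjusted p = 0.600 with an estimated correlation. The counts of both families were the same under both other scalings.

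None of the 4 families below was called with an estimated correlation (adjusted p = 0.312 for UGT and 0.806 for the others). Against seedling, of 9 GSTU glutathione transferase genes 7 were lower in stigma, such as GSTU20 (−3.42, SE 0.51) and GSTU25 (−3.04, SE 0.45, a bound), with adjusted p = 0.00446, and 6 were lower in ovary, with adjusted p = 0.00151. Of 24 UGT glycosyltransferase genes 13 were lower and 2 higher in stigma, and 12 lower and 2 higher in ovary, with adjusted p = 7.1e-04 each; UGT72E1 differed by −4.69 (SE 0.26) and −4.64 (SE 0.24), both bounds, and UGT85A3 was higher in stigma by 3.82 (SE 0.24). Of 69 chloroplast-encoded genes 24 were lower in stigma (adjusted p = 1.1e-07) and 42 in ovary (adjusted p = 6.7e-14), with none higher. The counts were 39 and 54 with chip lot as a block, 22 and 33 with quantile scaling and 23 and 46 with equal medians, and psaA, of photosystem I, differed by −3.75 (SE 0.22) and −3.11 (SE 0.20). Of 17 SCPL carboxypeptidase-like genes 6 were higher and 1 lower in ovary than in seedling (adjusted p = 0.0274), with scpl41 at 4.67 (SE 0.41, a bound). Bounds are for genes with signal under 17.2 in 1 tissue on average or on at least 2 arrays. Medians over all arrays were −1.78 for GSTU, −1.17 for UGT and −0.83 for chloroplast-encoded genes in stigma, and −1.31, −0.97 and −1.17 in ovary, with 0.55 for SCPL. Medians within chip lots 1 and 2, each with 1 seedling array, were −1.91 and −1.83 for GSTU, −1.23 and −1.09 for UGT and −1.09 and −1.31 for chloroplast-encoded genes in stigma. In ovary they were −1.55 and −1.42, −1.06 and −1.01, and −1.44 and −1.59, and 0.65 and 0.57 for SCPL. All medians kept their sign under both other scalings.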
